A study of Mus musculus with 14 samples.

How the data were processed

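Gene expression was measured on 14 single-colour arrays, each hybridised with RNA from 1 sort of mouse OT-I CD8+ T cells taken on day 6 of infection with Listeria expressing ovalbumin. The labels describe donor cells from fetal liver chimeras that were moved into congenic recipients, RNA extraction with TRIzol, amplification in several rounds and labelling with biotin. The arrays fell into 5 groups: wild-type (WT) KLRG1hi with 3 arrays, WT KLRG1lo with 5, and Id2KO, BimKO and Id2KOBimKO KLRG1lo with 2 each.

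The deposited values were the authors' RMA signal, an intensity on a linear scale, for 34760 probe sets on each array, and all columns were used. The labels name RMA without a version, and the submitters' notes name the mouse assembly mm9. The linear scale was read from the values themselves, and they were turned into log2 values with no offset. Scanner files were not used here, so the scale and the centring of the arrays against scanner values stay unknown. The direction of the scale was checked with Klrg1, the gene of the sorted protein, which was higher on each KLRG1hi array than on each KLRG1lo array.

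The median linear signal of all probe sets was 55.5, 51.8 and 49.7 on WT KLRG1hi arrays 1 to 3. It was 52.4, 49.2, 56.8, 56.0 and 54.6 on WT KLRG1lo arrays 1 to 5. The Id2KO arrays had medians of 49.5 and 49.6, the BimKO arrays 52.8 and 52.0, and the Id2KOBimKO arrays 49.8 and 53.2. No further normalization was applied for the values reported. For arrays, the number per group limits the precision.

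Of the probe sets, 21640 carried a single gene name, 1321 carried several and 11799 carried none. Names were brought up to date by Entrez number with a RefSeq table for assembly GRCm38.p6, in which 21553 of the probe sets were found. That table served only for names and for the order of genes along chromosomes, and no coordinates are given, because its assembly is not the mm9 of the notes. The probe set with the highest mean signal stood for each of 19937 genes. A gene was tested when its signal lay above the 40th percentile of the array on at least 2 arrays, which left 14438 genes.

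Differences were estimated with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading and writing. A model of group means was fitted to all 14 arrays at once, so that the 5 groups shared an estimate of the variance with 9 residual and 7.99 prior degrees of freedom. Tests were two-sided, without a variance trend, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Every p printed for a gene is an adjusted p from limma unless it is called unadjusted. The comparisons were WT KLRG1hi with WT KLRG1lo, Id2KO with WT, Id2KOBimKO with BimKO, the mean of these Id2 effects, BimKO with WT, Id2KOBimKO with Id2KO, Id2KOBimKO with WT, and the interaction of Id2 and Bim.

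The rule for naming genes, the 28 gene lists, the filter, the model and a first group of alternative settings were fixed before the data were examined. Apart from Id2, Bcl2l11 and Klrg1, the genes named were picked from the results by that rule. The lists covered effector and memory precursor genes, E and Id proteins, E protein targets, the Bcl-2 family, death receptors and caspases, cytotoxic genes, cytokines, homing receptors, cytokine receptors, T cell transcription factors, NK receptors, inhibitory receptors, follicular type genes, cell cycle, interferon-stimulated genes, glycolysis, TGF-beta responsive genes and immediate early genes. They also covered markers of B cells, monocytes and macrophages, neutrophils, dendritic cells, red cell precursors, platelets, NK cells, CD4 and regulatory T cells, and gamma delta T cells. Some lists share members: the NK cell markers share Klrb1c and Tyrobp, among others, with the NK receptors, and Gzmb with the effector and cytotoxic lists. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and with fry beside it. Camera compares a list with all other genes, while fry tests whether its members move on balance in 1 direction.

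The named genes were Id2, Bcl2l11 and Klrg1, then up to 10 genes with the largest rise and 10 with the largest fall among those that passed and whose arrays did not overlap between the groups. Predicted and clone names were passed over but counted. For the mean Id2 effect, the same sign in both Bim backgrounds was asked in place of separate arrays. Where fewer than 3 genes passed, the 5 smallest unadjusted p-values were taken and are given as values that did not pass. Up to 4 members of each list with the smallest unadjusted p were added.

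The alternative settings fixed in advance were no filter, a filter at the 60th percentile, quantile normalization, a robust fit with a variance trend, a replicate block, a fit on only the groups compared, the mean over probe sets, an offset of 16 before the log, a fold change of at least 1.5, and each array left out in turn. Further settings were added after seeing the data: the spread of each array as a covariate, cyclic loess, a term for 2 sets of arrays, subsets of the WT KLRG1lo arrays, and the sex-linked genes left out. Probe sets with several gene names or none were left out of the comparisons of genes, because their signal cannot be given to a single gene, and were tested apart.

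The steps were tested on simulated data with 14438 genes and 50 genes changed at each of 1.5-, 2-, 4- and 8-fold. For WT KLRG1hi with WT KLRG1lo, 21, 46, 49 and 50 were recovered. For Id2KO with WT these numbers were 9, 45, 50 and 50, for Id2KOBimKO with BimKO 7, 32, 50 and 50, and for the mean Id2 effect 19, 50, 50 and 50. Unchanged genes called in these simulations numbered 5, 13, 8 and 10 for the same comparisons in that order. The list tests called 5 of 5 lists shifted by 0.5 log2 and 0 of 20 lists left unshifted, with limma's camera in both forms and with fry. In these simulations each gene was drawn on its own, with no correlation between genes and no difference in spread between arrays. They therefore do not show how often the list tests err in the real data.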

Results

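The study profiled 14 samples of antigen-specific effector CD8+ T cells from mice on day 6 of infection, with 1 array per sample. The cells carried OT-I, a T cell receptor that recognises a peptide of ovalbumin, and the infecting Listeria expressed ovalbumin. KLRG1 is an inhibitory surface receptor that marks terminal effector cells, and the WT cells were sorted into KLRG1hi (3 arrays) and KLRG1lo (5 arrays). KLRG1lo cells were also sorted from donors labelled Id2KO, BimKO and Id2KOBimKO, with 2 arrays each. Id2 blocks E proteins, which are DNA-binding regulators of lymphocyte genes, and Bim, the product of Bcl2l11, promotes death through mitochondria. Median linear signals lay between 49.2 and 56.8 and upper quartiles between 124 and 151. Across genes tested, which are not independent replicates, log2 values of arrays from the same group correlated at 0.915 to 0.984, and the closest pair of all, at 0.992, came from different groups.

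The interquartile range of an array's log2 values, called its spread here, was 2.65 ± 0.20 (SD, n = 3) in WT KLRG1hi and 2.60 ± 0.15 (SD, n = 5) in WT KLRG1lo. It was 2.85 ± 0.02 in Id2KO, 2.66 ± 0.05 in BimKO and 2.71 ± 0.09 in Id2KOBimKO (SD, n = 2 each). The first principal component of the genes tested held 47.0% of the variance and correlated with the spread over the 14 arrays (r = 0.951, rho = 0.960, two-sided permutation p = 1e-05 for each, the smallest these permutations can give). Without the 2 arrays farthest from the median spread r was 0.919 and rho 0.937 (permutation p = 3e-05 and 4e-05). Background signal was also used to part the arrays into 2 sets that the labels do not name. The cut was made at the largest gap between array medians, 0.085 log2, a rule that always gives 2 sets. The median log2 signal of unnamed probe sets was 5.01 to 5.07 on 6 arrays and 5.16 to 5.39 on the other 8. WT KLRG1lo arrays 1 and 2 were in the first set, WT KLRG1lo arrays 3 to 5 and both BimKO arrays were in the second, and each other group had arrays in both. Within the sets, spread and first component correlated at r = 0.995 (n = 6, permutation p = 0.001) and 0.969 (n = 8, permutation p = 3e-04), with rho = 1 in both (permutation p = 0.003 and 9e-05). Nothing in the labels says that replicates come from separate animals, so the p-values measure the spread between these samples.

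Id2, the targeted gene, fell by 1.13 on the log2 scale in Id2KO against WT KLRG1lo cells (SE 0.19, adjusted p = 0.0162). Its log2 signal was 10.93 ± 0.20 (SD, n = 5) in WT KLRG1lo, 9.81 ± 0.10 (SD, n = 2) in Id2KO, 10.84 ± 0.13 (SD, n = 2) on arrays labelled BimKO and 9.74 ± 0.14 (SD, n = 2) on arrays labelled Id2KOBimKO. Between the last 2 groups the difference was -1.10 (SE 0.22), which did not pass (adjusted p = 0.587), and the mean over both Bim backgrounds fell by 1.11 (SE 0.15, adjusted p = 0.00137). Bcl2l11 was not lower on the arrays labelled BimKO: it was 7.51 ± 0.21 (SD, n = 2) there and 7.60 ± 0.19 (SD, n = 5) in WT KLRG1lo, a difference of -0.09 (SE 0.18, adjusted p = 0.882). It was 7.80 ± 0.30 (SD, n = 2) on arrays labelled Id2KOBimKO and 7.96 ± 0.10 (SD, n = 2) in Id2KO. Each of these genes had 1 probe set, whose position relative to the deleted sequence is not given in the sources used here. The Bim status of the arrays labelled BimKO or Id2KOBimKO therefore rests on their labels, while Id2 signal parted the Id2KOBimKO arrays (at most 9.84) from the BimKO arrays (at least 10.75). In Id2KO and Id2KOBimKO the Id2 signal was still far above the 5.01 to 5.39 of unnamed probe sets. It shows a lower Id2 signal, and that Id2 was absent rests on the labels as well. Klrg1 followed the sort, at 11.04 ± 0.50 (SD, n = 3) in KLRG1hi and 6.28 ± 0.29 (SD, n = 5) in WT KLRG1lo, and 5.24 and 6.83 on the arrays labelled Id2KOBimKO.

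Sex-linked transcripts set the Id2KO arrays apart from the other 12. Xist, the RNA of the inactive X chromosome, was 4.73 ± 0.37 (SD, n = 2) in Id2KO, while the other groups' means ran from 8.90 to 10.11. The Y-linked genes Eif2s3y, Uty and Kdm5d went the other way: Eif2s3y was 7.79 ± 0.57 (SD, n = 2) in Id2KO and 3.04 to 3.45 in the other groups, and Uty was 7.37 ± 0.59 (SD, n = 2) in Id2KO and 3.60 to 3.84 elsewhere. The low values were under those of unnamed probe sets, so the sizes of these differences are uncertain. The other Y-linked genes tested did not part these arrays: group means in Id2KO and WT KLRG1lo were 6.66 and 6.80 for Sry, 4.82 and 4.85 for Uba1y, and 6.34 and 6.06 for Srsy.

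**Figure D1:**
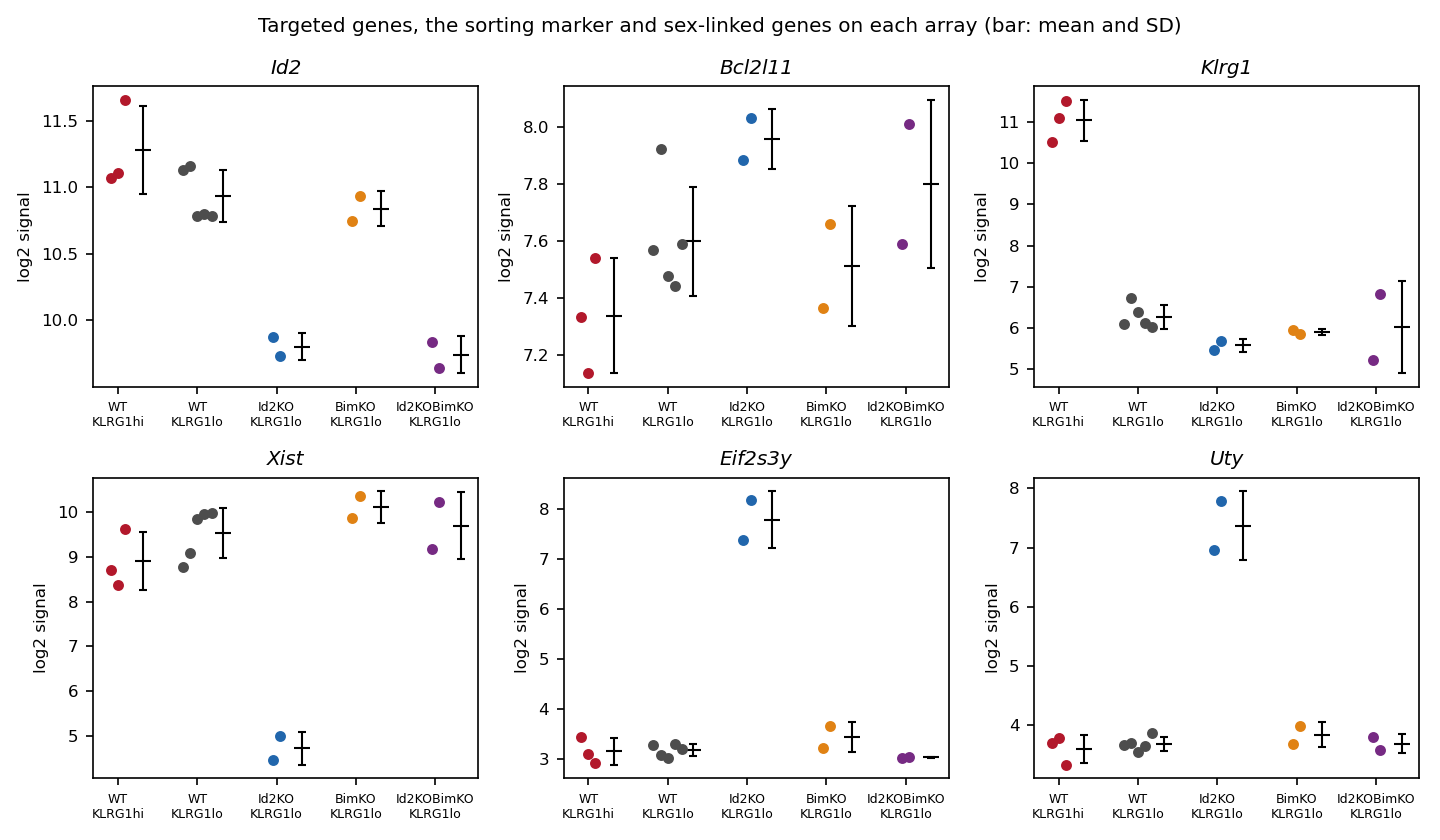
Log2 signal (vertical axis) of Id2, Bcl2l11, Klrg1, Xist, Eif2s3y and Uty on each of the 14 arrays (points), grouped by label along the horizontal axis, with the group mean and SD as bars. Id2 was lower in both groups labelled as lacking it, Bcl2l11 was not lower on the arrays labelled BimKO, and the sex-linked genes parted the Id2KO arrays from all others.

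The sorted WT populations were compared first, to describe what parts KLRG1hi from KLRG1lo effector cells. Beside Klrg1, which rose by 4.77 log2 (SE 0.28, adjusted p = 7.3e-08), named genes of the effector list were higher in KLRG1hi cells. Gzma, a granzyme of the cytotoxic granule, rose by 2.35 (SE 0.24, adjusted p = 3.46e-05), and Gzmb rose 2.82-fold (adjusted p = 0.00044). Cx3cr1, the fractalkine receptor, rose by 2.04 (SE 0.20, adjusted p = 2.99e-05), S1pr5, a receptor for blood-borne sphingosine phosphate, by 1.72 (SE 0.17), and Itgam, an integrin chain, by 2.32 (SE 0.20). Among transcription factor genes of the list, Zeb2 rose by 1.61 (SE 0.19), Prdm1 by 0.95 (SE 0.15) and Tbx21 by 0.83 (SE 0.17, adjusted p = 0.0203). The NK lectin-like receptors Klrb1c (2.92, SE 0.29), Klra3 (2.14, SE 0.25) and Klre1 (1.68), the surface protein Ly6a2 (2.65), the proteoglycan Esm1 (2.05), Gpx8 (1.71) and the chemokine gene Ccl9 (1.66) completed the largest rises. In WT KLRG1lo, Klra3 (5.18), Gpx8 (5.24) and Klre1 (4.03) were within or under the 5.01 to 5.39 of unnamed probe sets, so their rises are measured from background and their sizes and ranks are uncertain.

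Genes lower in KLRG1hi than in KLRG1lo cells included 7 of the 20 tested on the memory precursor list, Il7r, Ccr7, Myb, Ltb, Slamf6 and Tnfsf8 among them, and genes outside it. Dapl1 fell by 3.35 (SE 0.30, adjusted p = 1.21e-05) and the nuclear regulator Aff3 by 1.63 (SE 0.18). Il7r, the receptor chain for the survival cytokine IL-7, fell by 1.48 (SE 0.22, adjusted p = 0.0017). Ccr7, which guides cells into lymph nodes, fell by 1.38 (SE 0.22), and Gpr183, an oxysterol receptor that positions cells in lymphoid tissue, by 1.49 (SE 0.20). The regulator Myb fell by 1.36 (SE 0.16), the cytokine gene Ltb by 1.04 (SE 0.19), and the B cell follicle receptor Cxcr5 by 1.17 (SE 0.19, adjusted p = 0.00371). In KLRG1hi, Dapl1 (4.60), Cxcr5 (4.74) and Tnfsf8 (5.18) were under or within the level of unnamed probe sets, so the sizes and ranks of these falls are uncertain. Others among the largest falls were Nsg2 (-1.51), Slamf6 (-1.43), Actn1 (-1.38) and Inpp4b (-1.35). Id2 itself was at 0.35 (adjusted p = 0.682) and Id3, a relative with related function, at -0.84 (SE 0.28, adjusted p = 0.287), and neither passed.

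In all, 136 genes passed, 98 higher and 38 lower in KLRG1hi, with folds from 1.47 to 27.2, and 1039 had an unadjusted p under 0.05 where 722 are expected by chance. Within the 2 array sets the median change of these 136 genes was 0.80 and 1.13, and their sign there was fixed, as no KLRG1hi array overlapped a KLRG1lo array for any of them. The count was 45 without WT KLRG1hi replicate 2, and 89, 84, 87 and 73 without WT KLRG1lo replicates 1, 3, 4 and 5. It ranged from 36 against WT KLRG1lo arrays 1 and 2 alone to 376 with the array spread as a covariate. The balance turned to 16 higher and 20 lower against those 2 arrays, and to 69 higher and 103 lower without WT KLRG1hi replicate 3.

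**Figure D2:**
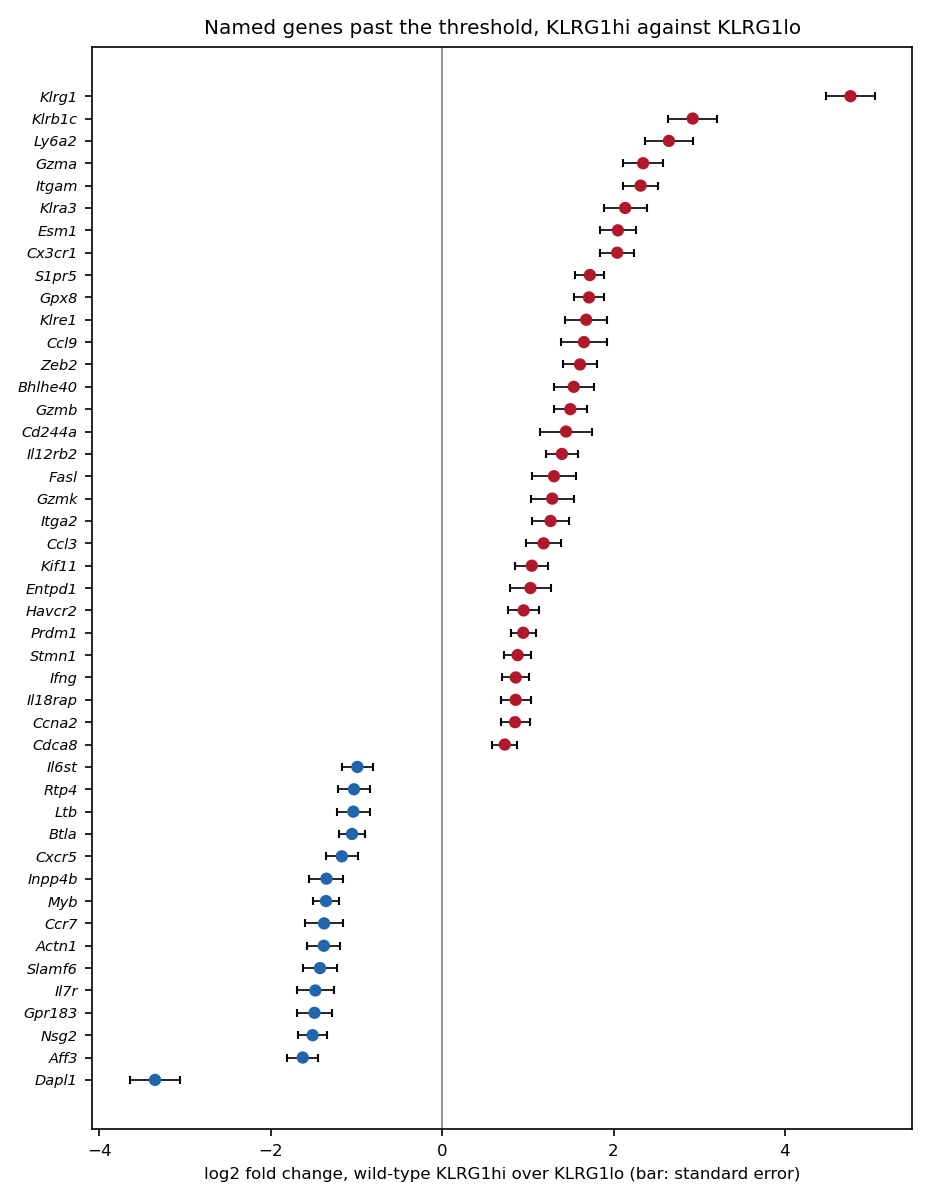
Log2 fold change of WT KLRG1hi over WT KLRG1lo (horizontal axis; points, with the standard error as bars) for the 45 named genes that passed, in order of change. Klrg1 is at the top with 4.77 and Dapl1 at the bottom with -3.35, where the place of Dapl1, Cxcr5, Klra3, Gpx8 and Klre1 is uncertain because 1 group was at background.

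The fixed lists gave 14 calls between KLRG1hi and KLRG1lo, 6 of them higher and 8 lower. Of 22 effector genes tested, a list that includes Klrg1, 17 rose and 0 fell, and 22 were higher when adjusted over the list alone (median 1.24, list adjusted p = 1.88e-60). Of 44 cell cycle genes, 9 rose and 0 fell, 31 adjusted over the list alone (median 0.59, list adjusted p = 7.41e-37), among them the mitotic motor Kif11 (1.05), Stmn1 (0.88) and the cyclin Ccna2 (0.85). Of 20 memory precursor genes, 7 fell and 0 rose, 15 adjusted over the list alone (median -0.51, list adjusted p = 2.61e-22). Of 13 follicular type genes, 3 fell and 0 rose, 5 adjusted over the list alone (median -0.32, list adjusted p = 4.64e-11), with Btla, an inhibitory receptor, at -1.05. These 4 lists held with an estimated correlation, at adjusted p = 0.00357, 0.00969, 0.00707 and 0.00141 in the order given.

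The other 10 list calls between the WT populations were lost with an estimated correlation. Of 18 cytotoxic genes 5 rose and 0 fell, 9 adjusted over the list alone (median 0.60), with Fasl at 1.31, Gzmk at 1.29 and the pore-forming Prf1 at 1.18 (adjusted p = 0.108 with an estimated correlation). Of 15 NK receptors, which include Klrg1, 5 rose and 1 fell, 9 and 1 adjusted over the list alone (median 0.67; adjusted p = 0.079 with an estimated correlation). The NK cell markers, of which 3 of 9 rose, had a median of 0.22 (adjusted p = 0.108 with an estimated correlation). Of 24 homing receptors 4 rose and 3 fell, 5 and 4 adjusted over the list alone (median 0.19; adjusted p = 0.556 with an estimated correlation). Camera at the preset correlation called this list in 3 of 6 settings of scaling and filter, at adjusted p = 0.0311 to 0.0854. Among 25 interferon-stimulated genes Rtp4 fell by 1.03 (SE 0.18), the single gene to pass, and the list's median was -0.27 (adjusted p = 0.161 with an estimated correlation). Of 17 E protein targets 2 fell (median -0.03; adjusted p = 0.108 with an estimated correlation). Markers of other cells were lower in KLRG1hi, with none past the test for a single gene. The medians were -0.31 for B cells, -0.24 for monocytes and macrophages, -0.29 for neutrophils and -0.48 for red cell precursors (adjusted p = 0.208, 0.391, 0.341 and 0.325 with an estimated correlation). Cd74, the invariant chain of antigen-presenting cells, was 5.32 ± 0.38 (SD, n = 3) in KLRG1hi and ranged from 5.73 to 8.73 over the 5 WT KLRG1lo arrays.

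The remaining 14 lists were not called between the WT populations. Their adjusted p-values were 0.619 for E and Id proteins, 0.491 for the Bcl-2 family, 0.156 for death receptors and caspases, 0.201 for cytokines and chemokines, 0.877 for cytokine receptors, 0.113 for T cell transcription factors (called lower in 3 of 6 settings of scaling and filter, at 0.0348 to 0.116) and 0.542 for inhibitory receptors. They were 0.326 for glycolysis, 0.896 for TGF-beta responsive genes, 0.847 for immediate early genes, and 0.0946, 0.212, 0.135 and 0.583 for markers of dendritic cells, platelets, CD4 or regulatory T cells and gamma delta T cells. Single members still passed: 4 cytokine genes rose, Ifng among them (0.86, SE 0.16), and the receptor chain Il12rb2 rose by 1.40 (SE 0.19) while Il6st fell by 0.99. Among inhibitory receptors Havcr2 (0.95), Cd244a (1.45) and the ectoenzyme Entpd1 (1.03) rose while Btla fell. In 21 alternatives run, Havcr2 stayed past the threshold in 15, Cd244a in 14 and Entpd1 in 9, and Btla in all. For that list the median was -0.08 and the mean 0.04. Median and mean also differed in sign, both near 0, for E and Id proteins (0.01 and -0.07), TGF-beta responsive genes (0.01 and -0.01) and cytokine receptors (-0.002 and 0.009), and for immediate early genes the test pointed down while the median was 0.04.

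The Id2KO and WT KLRG1lo cells were compared to describe how cells labelled Id2KO differ within the KLRG1lo population. Cxcr5 rose by 1.80 log2 (SE 0.22, adjusted p = 0.000547), from 5.91 ± 0.27 (SD, n = 5) to 7.72 ± 0.12 (SD, n = 2). Cx3cr1 fell by 1.77 (SE 0.22, adjusted p = 0.00105), from 8.34 ± 0.22 (SD, n = 5) to 6.57 ± 0.08 (SD, n = 2). Myb rose by 1.17 (SE 0.18, adjusted p = 0.00912), the actin crosslinker genes Actn1 by 1.46 (SE 0.22, adjusted p = 0.00866) and Pls1 by 1.24 (SE 0.20), the sodium pump subunit gene Atp1b1 by 1.24 (SE 0.18) and the inhibitory receptor gene Ctla4 by 1.38 (SE 0.25, adjusted p = 0.0306, past the threshold in 10 of 20 alternatives run). Wdr12 (1.53), Apobec2 (1.37) and Cd163l1 (1.15) also rose, and S1pr5 fell by 1.05 (SE 0.19, adjusted p = 0.04). In these 20 alternatives Wdr12 stayed past the threshold in 13, Apobec2 in 15, Cd163l1 in 12 and S1pr5 in 11. Id3 was at 1.38 (SE 0.32, adjusted p = 0.156), Btla at 0.88 (adjusted p = 0.0601) and Zeb2 at -0.78 (adjusted p = 0.275), and these did not pass. Arrays labelled BimKO, with Id2 at -0.09, were set against the same WT arrays. Cx3cr1 was at -0.82 there, S1pr5 at -0.59, Cxcr5 at 0.60, Ctla4 at 0.68 and Myb at 0.63, and none passed. Pls1, Wdr12 and Apobec2 on the BimKO arrays lay within the range of the WT KLRG1lo arrays. A part of the Id2KO change of Cx3cr1, S1pr5, Cxcr5, Ctla4 and Myb may therefore not be particular to Id2 loss.

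Between Id2KO and WT KLRG1lo cells 16 genes passed, 12 higher and 4 lower, of which 4 were sex-linked: Eif2s3y, Uty, Kdm5d and Xist. The 12 others, 9 higher and 3 lower with Id2 included, had median changes of 1.08 and 1.52 within the 2 array sets, where their sign was fixed because the groups' arrays did not overlap. An unadjusted p under 0.05 was seen for 2613 genes, and the smallest fold that passed was 2.06. The count was 7 and 4 without Id2KO replicates 1 and 2 and 39 without WT KLRG1lo replicate 2. Against WT KLRG1lo arrays 1 and 2 alone it was 6, and against arrays 3 to 5 alone it was 708.

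As groups, 13 lists were called in Id2KO against WT, 8 higher and 5 lower, and none held with an estimated correlation. Of 20 memory precursor genes 1 rose, Myb, and 8 were higher when adjusted over the list alone (median 0.34; adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation). Of 13 follicular type genes 1 rose, Cxcr5, and 5 were higher and 1 lower when adjusted over the list alone (median 0.41; adjusted p = 0.0345, and adjusted p = 0.39 with an estimated correlation). Fry called this list at adjusted p = 0.0017. Over 6 settings of scaling and filter, which called these lists throughout, the medians ran from 0.12 to 0.36 and from 0.15 to 0.41. Of 44 cell cycle genes none passed and 33 were negative (median -0.33; adjusted p = 9.15e-05, and adjusted p = 0.39 with an estimated correlation), and each setting called the list, with medians from -0.39 to -0.28. Of 25 interferon-stimulated genes none passed and 21 were positive (median 0.38; adjusted p = 0.00129, and adjusted p = 0.39 with an estimated correlation), and over these settings the median ran from 0.09 to 0.38, with 5 of 6 calling the list. Effector genes as a list were not called (median -0.03, adjusted p = 0.199; 2 of 22 fell, Cx3cr1 and S1pr5), but were called lower in 3 of 6 settings of scaling and filter, with medians down to -0.40 and adjusted p-values from 7.57e-14 to 0.504. NK receptors (adjusted p = 0.0817) were likewise called lower in 3 of 6 (7.03e-09 to 0.0962). E and Id proteins (0.0857), a list that includes the targeted Id2, were called lower in 2 of 6 (0.0211 to 0.346). E protein targets (0.231) were called in none.

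Cytokine receptors (median 0.43), death receptors and caspases (0.28), cytotoxic genes (0.35), homing receptors (0.35) and glycolysis (0.39) were also called higher in Id2KO. Their adjusted p-values were 0.39, 0.442, 0.457, 0.457 and 0.457 with an estimated correlation. They were called in 4, 4, 3, 3 and 3 of 6 settings. The direction of the last 3 of these lists flipped in 1 of the settings, as did the median of cytokine receptors, at -0.02. Other cells' markers were called lower: B cells (median -0.39), monocytes and macrophages (-0.43), neutrophils (-0.54) and dendritic cells (-0.36), at adjusted p = 0.414, 0.39, 0.39 and 0.39 with an estimated correlation, and in 4, 5, 4 and 4 of 6 settings. Cd74 was 5.14 ± 0.67 (SD, n = 2) in Id2KO and Lyz2, a macrophage lysozyme gene, 5.21 against 6.55 ± 1.25 (SD, n = 5) in WT KLRG1lo. The lists called higher had median signals of 6.74 to 9.16 and those called lower 5.58 to 6.90 on the log2 scale, and the Id2KO arrays had the widest mean spread. With a filter at the 60th percentile the median change of all genes tested was 0.197, against 0.03 with the filter used.

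Loss of Id2 was also compared in cells labelled BimKO, to ask whether its effect is present when Bim is absent. Id2 was lower on each Id2KOBimKO array than on each BimKO array, but its remaining signal was well above that of unnamed probe sets. That Id2 and Bim were absent rests on the labels. None of 14438 genes passed in limma for Id2KOBimKO against BimKO, and the smallest adjusted p was 0.306. An unadjusted p under 0.05 was seen for 262 genes where 722 are expected by chance, and why there were fewer was not tested. With 2 arrays in each group and a variance shared with the other groups, the lack of calls does not show that the effect is absent. The smallest unadjusted p-values belonged to Pls1 (1.36, SE 0.24), the amino acid transporter gene Slc43a1 (1.13, SE 0.21), Id2 (-1.10, SE 0.22), the receptor kinase gene Erbb3 (1.19, SE 0.25) and the ubiquitin ligase gene Rnf144a (-1.09, SE 0.23), none of which passed. Cxcr5 was at 0.76 (SE 0.26), Cx3cr1 at -0.62 (SE 0.27) and Id3 at 0.98 (SE 0.38). Without BimKO replicate 1 the count was 3.

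Genes called in Id2KO were looked up in this comparison, which shares no array with it. Of the 12 that were not sex-linked, 12 had the same sign and 10 passed when adjusted over the list alone, with a median change of 0.77 in the Id2KO direction against 1.31 in Id2KO. Id2 was 1 of these 12, and its fall follows from its targeting in both comparisons. Across all 14438 genes the fold changes of the Id2 comparisons correlated at r = 0.0937 and rho = 0.0761, where genes are not independent replicates. That r fell to -0.0990 without Id2KOBimKO replicate 1 and to -0.121 without BimKO replicate 1, and was 0.246 and 0.335 without replicate 2 of each. The interaction, which tests whether the Id2 effect differed between Bim backgrounds, called 4 genes, the sex-linked Eif2s3y, Kdm5d, Uty and Xist, and 616 had an unadjusted p under 0.05.

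The mean of both comparisons had smaller standard errors than either alone, but it includes Id2KO against WT, where sex-linked genes also differed. Nrp1, a semaphorin and VEGF coreceptor, rose by 1.44 (SE 0.22, adjusted p = 0.00581), Pls1 by 1.30 (SE 0.15, adjusted p = 0.00052), Cxcr5 by 1.28 (SE 0.17, adjusted p = 0.00137) and Actn1 by 1.25 (SE 0.17, adjusted p = 0.00248). Slc43a1 rose by 0.97 (SE 0.14), Itgam by 1.03 (SE 0.18), Myb by 0.86 (SE 0.14) and Btla by 0.72 (SE 0.13, adjusted p = 0.0261). The IL-6 receptor gene Il6ra rose by 0.66 (SE 0.12), but stayed past the threshold in 10 of 24 alternatives run, and Btla in 13. Wdr12 (1.18), Apobec2 (1.13), Chil5 (1.06) and Cd163l1 (0.96) rose as well. Cx3cr1 fell by 1.20 (SE 0.18, adjusted p = 0.00367) and Rnf144a by 1.04 (SE 0.15, adjusted p = 0.00367). Id3 was at 1.18 (SE 0.25, adjusted p = 0.0811), S1pr5 at -0.67 and Ctla4 at 0.89, none past the threshold.

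This mean effect called 26 genes, 22 higher and 4 lower, or 22 with the sex-linked genes left out, and 1027 had an unadjusted p under 0.05. The count was 17 and 13 without Id2KO replicates 1 and 2, 14 and 15 without Id2KOBimKO replicates 1 and 2, and 15 against WT KLRG1lo arrays 1 and 2 alone. With the array spread as a covariate it was 52, of which 25 were lower.

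**Figure D3:**
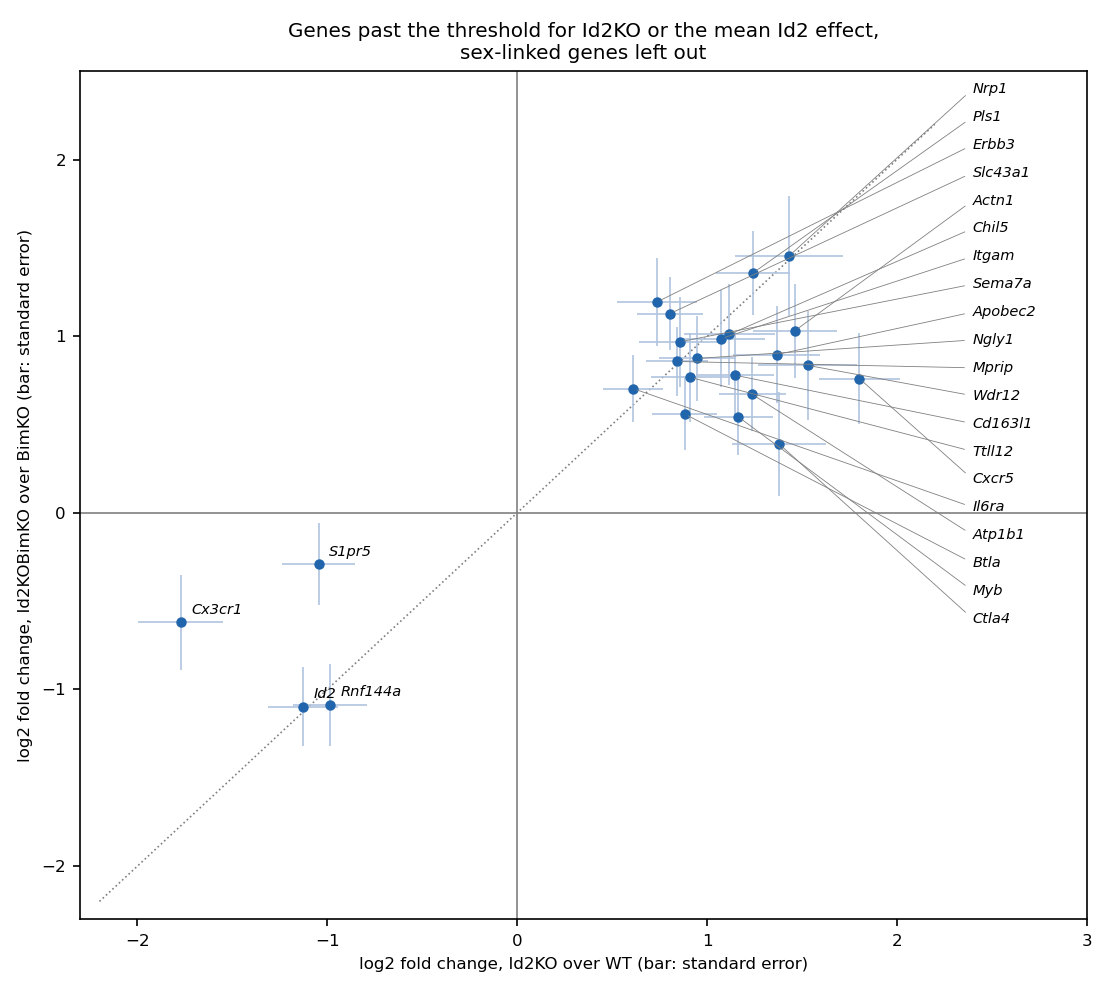
Log2 fold change of Id2KO over WT (horizontal axis) and of Id2KOBimKO over BimKO (vertical axis) for genes that passed in Id2KO or for the mean Id2 effect, sex-linked genes left out; bars are standard errors and the dotted line marks equal change. All points lie in the quadrants of equal sign, and genes picked for their change in Id2KO sit mostly nearer 0 on the vertical axis. The mean Id2 effect averages both axes, so genes picked by it tend to share a sign by selection. Their equal sign therefore cannot show that the effect recurs in both Bim backgrounds. Id2 is among the points, and its fall follows from its targeting. Across all 14438 genes tested the axes correlated at r = 0.0937.

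Among the lists, 15 were called for the mean Id2 effect, 7 higher and 8 lower, and none held with an estimated correlation. Interferon-stimulated genes had a median of 0.30 with 24 of 25 positive, and 3 were higher when adjusted over the list alone (adjusted p = 0.367 with an estimated correlation). Follicular type genes had a median of 0.30, with Cxcr5 and Btla past the test (adjusted p = 0.367 with an estimated correlation, fry adjusted p = 0.003). Cell cycle genes had a median of -0.27 with 8 of 44 positive (adjusted p = 0.367 with an estimated correlation). NK receptors had a median of -0.53, with none past the test and 4 lower when adjusted over the list alone (adjusted p = 0.385 with an estimated correlation). NK cell markers had a median of -0.23 (adjusted p = 0.385 with an estimated correlation). Each of 6 settings of scaling and filter called these lists. The medians ran from 0.129 to 0.299 for interferon-stimulated genes and from 0.114 to 0.302 for follicular type genes. They ran from -0.348 to -0.226 for cell cycle genes, -0.615 to -0.266 for NK receptors and -0.477 to -0.2 for NK cell markers. Effector genes (median -0.07) were not called, but were called lower in 4 of 6 settings of scaling and filter, at adjusted p-values from 1.01e-09 to 0.215. Markers of other cells were lower beside these lists: monocytes and macrophages (median -0.33, called in 5 of 6 settings), neutrophils (-0.33, in 3 of 6), red cell precursors (-0.26, in 1), dendritic cells (-0.24, in 1) and B cells (-0.20, in 2, with a positive median in 1 setting). Their adjusted p-values were 0.385 for monocytes and macrophages and 0.566 for the others with an estimated correlation. The other lists called higher were memory precursor genes (median 0.24, in 2 of 6 settings), cytokine receptors (0.20, in 3), cytotoxic genes (0.23, in 2), death receptors and caspases (0.16, in 3) and glycolysis (0.22, in 2), each at adjusted p = 0.566 with an estimated correlation. The direction of the last 4 flipped in 1 setting. In the comparison of arrays labelled Id2KOBimKO with BimKO 4 lists were called: NK receptors (median -0.73), NK cell markers (-0.39, 9 of 9 negative), cell cycle (-0.24) and interferon-stimulated genes (0.22). Their adjusted p-values were 0.235, 0.235, 0.294 and 0.365 with an estimated correlation. The NK receptor and NK cell marker lists share members, Klrb1c among them, so their calls are not separate results.

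Bim was addressed by comparing KLRG1lo cells labelled BimKO with WT, a direction that rests on labels that Bcl2l11 signal did not check. None of 14438 genes passed in limma, 998 had an unadjusted p under 0.05, and the smallest adjusted p was 0.374. The smallest unadjusted p-values were those of the kinase gene Ttbk2 (1.10, SE 0.19), the DNA sensor gene Aim2 (1.08, SE 0.20), the peptide transporter gene Slc15a2 (1.02, SE 0.22), Nsg2 (0.84, SE 0.20) and the zinc finger gene Zbtb20 (1.09, SE 0.25, from 5.31 in WT, the level of unnamed probe sets), and none passed. Of the Bcl-2 family, Bmf, a promoter of apoptosis, was at -0.69 (SE 0.22) and the survival gene Bcl2 at 0.59 (SE 0.26), and the family as a list was not called (median -0.08, adjusted p = 0.432). Memory precursor genes were called, with 19 of 20 positive and a median of 0.25 (adjusted p = 3.19e-05, and adjusted p = 0.351 with an estimated correlation). Inhibitory receptors (median 0.25), cytokine receptors (0.17) and markers of CD4 or regulatory T cells (0.14) were the other calls (adjusted p = 0.704, 0.704 and 0.328 with an estimated correlation). Follicular type genes were called higher in 4 of 6 settings of scaling and filter (adjusted p = 0.0161 to 0.0896) and effector genes lower in 3 of 6 (9.15e-05 to 0.136). Without BimKO replicate 1, 8 genes passed, and as both BimKO arrays were in the second array set, no value within the first could be given.

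Against WT KLRG1lo, the arrays labelled Id2KOBimKO had 9 genes past the threshold, 7 higher and 2 lower. Cxcr5 rose by 1.36 (SE 0.22, adjusted p = 0.0182), and Actn1 (1.28), Pls1 (1.23), Ttbk2 (1.22), Atp1b1 (1.20), Myb (1.17) and Slc43a1 (1.04) rose with it. Cx3cr1 fell by 1.44 and Id2 by 1.19. Ttbk2 is on the same chromosome as Bcl2l11, so for it an effect of flanking DNA cannot be told from one of Bim loss. The median changes of the 9 genes within the 2 array sets were 1.31 and 1.25, with the sign again fixed by arrays that did not overlap. The count was 0 in limma without WT KLRG1lo replicate 1, 4 or 5 or without either Id2KOBimKO array, and 0 against WT KLRG1lo arrays 1 and 2 alone. The lists called numbered 11, among them interferon-stimulated genes (median 0.32; adjusted p = 0.388 with an estimated correlation), follicular type genes (0.35; adjusted p = 0.0577 with an estimated correlation) and effector genes (-0.23; adjusted p = 0.524 with an estimated correlation). Lists of cell type markers moved with them: NK cells (median -0.25, called in 6 of 6 settings), neutrophils (-0.29, in 4 of 6) and CD4 or regulatory T cells (0.21, in 6 of 6). Their adjusted p-values were 0.456, 0.506 and 0.343 with an estimated correlation. The NK cell list shares Gzmb with the effector list and Klrb1c with the NK receptors, so its change need not come from other cells. Against Id2KO, the arrays labelled Id2KOBimKO differed in 4 genes, all sex-linked, and 116 genes had an unadjusted p under 0.05.

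The difference between KLRG1hi and KLRG1lo cells was set beside the Id2 effect to ask whether the genes overlap. Among genes lower in KLRG1hi, 6 were higher for the mean Id2 effect (Actn1, Btla, Cxcr5, Il6ra, Myb and Slc43a1), where independent lists would share 0.05. Of genes higher in KLRG1hi, Cx3cr1 was lower for the mean Id2 effect, while Apobec2 and Itgam were higher, against 0.129 for independent lists. As groups, the 38 genes lower in KLRG1hi had a median of 0.53 in Id2KO, 35 of them positive (adjusted p = 0.145 with an estimated correlation), and -0.09 in Id2KOBimKO against BimKO (adjusted p = 0.77 with an estimated correlation). The 98 genes higher in KLRG1hi had medians of -0.14 and -0.21 there (adjusted p = 0.562 and 0.292 with an estimated correlation). In BimKO against WT, where Id2 was not lower, the 38 genes had a median of 0.38, with 37 positive (adjusted p = 0.106 with an estimated correlation). The median of the 98 genes was 0.03 in that comparison.

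These comparisons with Id2KO share the WT KLRG1lo arrays, which alone makes fold changes correlate. Across 14438 genes, which are not independent replicates, r was 0.136, rho was 0.227 and the covariance was 0.0116. Simulated groups without change, set against shared controls, gave r = 0.327 (0.305 to 0.354 over 100 simulations) and a covariance of 0.0124. The simulated noise was drawn for each gene on its own, without the array spread that genes share in the data. The narrow simulated range therefore cannot be used to judge the observed r. With the WT KLRG1lo arrays split in 20 ways so that no control was shared, r ranged from -0.479 to 0.311 with a median of 0.0250, and 9 splits were negative. Against Id2KOBimKO over BimKO, which shares no array, r was -0.0201 and rho was 0.0304. The r with Id2KO was 0.496 without WT KLRG1hi replicate 1, 0.386 without WT KLRG1lo replicate 2 and -0.294 without WT KLRG1hi replicate 3.

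**Figure D4:**
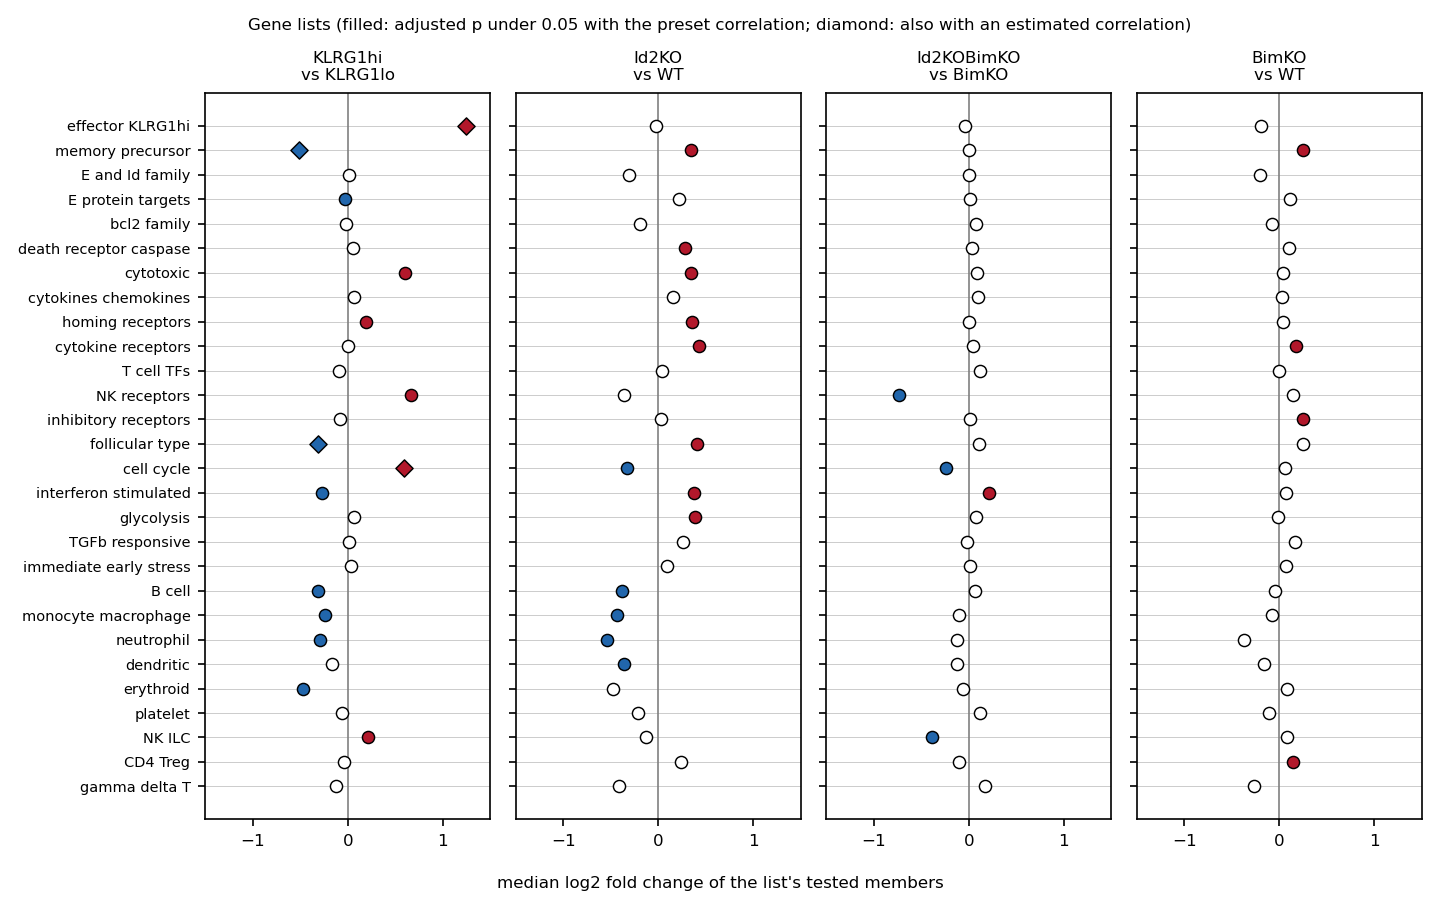
Median log2 fold change (horizontal axes) of the tested members of each of the 28 gene lists (vertical axis) in 4 comparisons; filled points passed with the preset correlation and diamonds also with an estimated correlation. Diamonds appear in the comparison of KLRG1hi with KLRG1lo, and in Id2KO against WT the directions of the cytotoxic, homing and glycolysis lists flipped in 1 of 6 settings of scaling and filter.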

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

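The tests on sex-linked genes and on genes beside the targeted loci were chosen only after the results were seen, as were the terms for array spread and array set and the subsets of WT KLRG1lo arrays.

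Of 295 named genes, 12 had a WT KLRG1lo array that stood apart from the other 4, with a gap over 0.71 of the range of the 5 arrays. Chance alone marks about 1 in 20 (5%) of such groups. The log2 values of array 2 were 5.934 for Bik (others 6.401 to 6.586), 7.169 for Fasl (others 6.507 to 6.663) and 5.009 for Siglech (others 5.226 to 5.308). Array 3 had 6.321 for Egr1 (others 6.596 to 6.67), 6.827 for Tgif1 (others 7.262 to 7.423), 7.468 for Cdk6 (others 8.112 to 8.34) and 6.371 for Oasl2 (others 6.054 to 6.129). Array 4 had 6.394 for Ccl9 (others 5.321 to 5.617), 7.328 for Lcn2 (others 5.384 to 5.937) and 7.768 for Tyrobp (others 6.606 to 6.743). Array 5 had 6.808 for Tnfsf8 (others 6.393 to 6.5), and array 1 had 8.787 for Cxcr4 (others 8.305 to 8.354).

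The limma test of a difference between the Id2 comparisons in the 2 Bim backgrounds called 4 sex-linked genes: Eif2s3y by -5.021 (adjusted p = 2.26e-07), Uty by -3.835 (adjusted p = 6.13e-06), Kdm5d by -3.058 (adjusted p = 0.00388) and Xist by 4.375 (adjusted p = 0.00345). They set the Id2KO arrays apart from all others and are weighed below as a difference in sex, not as an Id2 effect that depends on Bim, and their low signals were under that of unnamed probe sets, which leaves these sizes uncertain. Among 7846 probe sets with several gene names or none, which the comparisons of genes did not use, 3 passed between WT KLRG1hi and KLRG1lo, 2 in Id2KO against WT, 2 for the mean Id2 effect, 1 between Id2KOBimKO and Id2KO and 1 for the interaction.

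Sex-linked genes form the first pattern weighed, and all 4 that were called in Id2KO against WT separated the 2 Id2KO arrays from the other 12, while the Y-linked Sry, Uba1y and Srsy, which were tested and not called, did not. That is consistent with male cells in Id2KO and female cells elsewhere, which the labels do not state. A swap with WT arrays is argued against by Id2 itself, since the lowest array with intact Id2 was 0.870 log2 above the highest Id2KO array. Sex as the whole cause of the other 12 calls is argued against by Id2KOBimKO against BimKO. Mean Xist was 9.69 and 10.11 in the groups compared there. These genes moved by a median of 0.769 in the Id2KO direction, and 10 of the 12 passed in limma when adjusted over the list alone. The SE of the mean, 0.0871, was taken over genes measured on the same arrays, which are not independent replicates. The 12 include Id2, whose fall follows from its targeting in both comparisons. A part of each Id2KO change, and so of the mean Id2 effect, may still come from sex, and no test here removes it.

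Genes beside the targeted loci form the second pattern, with order taken from assembly GRCm38.p6. Of the 100 tested genes nearest Id2, 7 had an unadjusted p under 0.01 for the mean Id2 effect, more than in 99.3% of 1239 other windows: Lpin1, Adam17, Klf11, Rrm2, Rnf144a, Adi1 and Prkar2b. Only Rnf144a, the tested gene next to Id2, passed the adjusted threshold, and Adi1 was at adjusted p = 0.0511. Of the 100 nearest Bcl2l11, 2 did so for a mean Bim effect chosen after the data were seen (Slc28a2b and Slc4a11), more than in 97.0% of 1237 windows. Flanking DNA carried with the targeted Id2 allele, or flanking DNA carried with the targeted Bcl2l11 allele, may account for these, while an effect of Id2 on its own neighbourhood was not tested. The windows overlap one another, so the percentages do not stand for independent windows. Ttbk2, which passed for the mean Bim effect, lies 76 tested genes from Bcl2l11 on the same chromosome, outside its window.

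The third pattern is that the Id2KO count rests on which WT KLRG1lo arrays are used: 6 genes against arrays 1 and 2, and 708 against arrays 3 to 5, of which 83.9% were higher. A difference in array spread may account for most of the 708. With the spread as a covariate 9 genes passed, the median change of the same genes went from 0.883 to 0.374 while its standard error went from 0.212 to 0.244, and cyclic loess left 38. An additive difference between the 2 array sets as the whole cause is argued against by the 4027 genes that passed with a term for the set. No biological explanation was tested, and the division of arrays 1 and 2 from 3 to 5, at 1502 genes with at most 4 in any other pairing, is also that of the array sets.

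Chance cannot be excluded by regrouping the arrays. For WT KLRG1hi against KLRG1lo, fitted on these arrays alone, the real split gave 78 genes, the highest other 1031 (KLRG1hi array 1 with KLRG1lo arrays 3 and 4), and 3 of 56 splits gave as many as the real one. For Id2KO against WT the real split gave 26, the highest other 1187 (KLRG1lo arrays 3 and 4 against the rest), and 2 of 21 gave as many. Splits that call many more genes than the real one point to a structure of the samples: the arrays these parted off had the smallest spreads, at 2.44, 2.46 and 2.48. The remaining split above the real 78 set KLRG1lo arrays 3, 4 and 5 apart with 141 genes, which are the WT KLRG1lo arrays of the second array set, and the spread of array 5 was 2.57.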

How the results depend on the processing

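The array spread, cyclic loess and array set terms, the subsets of WT KLRG1lo arrays and the omission of sex-linked genes were chosen only after the results were seen. In the alternatives run, no named gene that had passed changed direction: 862 of 944 values between the WT populations stayed past the threshold, as did 256 of 320 for Id2KO against WT, 363 of 432 for the mean Id2 effect, 60 of 60 for Id2KOBimKO against Id2KO, 111 of 180 for Id2KOBimKO against WT and 94 of 96 for the interaction. That no direction changed was largely fixed beforehand and is no support for these genes. The filters, the variance settings and the fit on only the groups compared do not alter a fold change. Where the arrays of 2 groups do not overlap, leaving arrays out cannot turn the sign. Where a count moved, the cause was not tested unless stated. Signal near the background limits what the filter at the 40th percentile can keep, and where leaving out an array left a group with 1, that array was assumed to vary like the other groups.

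Between WT KLRG1hi and KLRG1lo (136 genes, 98 higher), quantile normalization gave 225 (155 higher), only the groups compared 78, the spread covariate 376 (223 higher, 153 lower), cyclic loess 236 (150 higher), WT KLRG1lo arrays 1 and 2 only 36 (16 higher, 20 lower) and arrays 3 to 5 only 255 (214 higher). Leaving out 1 array gave 45 (without WT KLRG1hi replicate 2) to 179 (without replicate 1). Without WT KLRG1hi replicate 3 it gave 172, of which 103 were lower. For Id2KO against WT (16), the spread covariate lost 6 of the 16 and quantile normalization 3, only the groups compared gave 26, the subsets of WT arrays 6 and 708, and leaving out 1 array 4 to 39. For Id2KOBimKO against BimKO (0 in limma, 262 at an unadjusted p under 0.05), quantile normalization gave 1, the spread covariate 4, cyclic loess 2, and leaving out 1 array 0 to 3.

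For the mean Id2 effect (26), the spread covariate gave 52 (27 higher, 25 lower), WT KLRG1lo arrays 1 and 2 only 15, and leaving out 1 array 13 (without Id2KO replicate 2) to 31 (without WT KLRG1lo replicate 2). For BimKO against WT (0 in limma, 998 at an unadjusted p under 0.05) leaving out 1 array gave 0 to 8. For Id2KOBimKO against Id2KO (4), only the groups compared gave 7, and leaving out the sex-linked genes 0, by construction. For Id2KOBimKO against WT (9), the spread covariate gave 24 (15 higher), cyclic loess 17 (12 higher), WT KLRG1lo arrays 1 and 2 only 0, and leaving out 1 array 0 to 13. The interaction (4) gave 0 with the sex-linked genes left out, by construction, and 3 to 6 with 1 array left out. The correlation of Id2 effects ranged from -0.121 to 0.335 with 1 array left out (without BimKO replicate 1 and 2), and that of the KLRG1hi difference with the Id2 effect from -0.294 to 0.496 (without WT KLRG1hi replicate 3 and 1).

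Lists called with an estimated correlation were 4, 0, 0, 0, 0 and 0, and with fry 8, 1, 0, 1, 0 and 1, for WT KLRG1hi against KLRG1lo (14), Id2KO against WT (13), Id2KOBimKO against BimKO (4), the mean Id2 effect (15), BimKO against WT (4) and Id2KOBimKO against WT (11). With the spread covariate Id2KO against WT called 6. The mean Id2 effect called 8 with quantile normalization, 6 with the spread covariate and 8 with cyclic loess, and BimKO against WT called 7 with the array set term.

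The labels do not say that replicate numbers pair the samples. After removal of group means, arrays of the same number in different groups correlated at -0.524 to 0.410, with WT KLRG1lo and Id2KO at 0.209 and 0.156 and WT KLRG1hi and KLRG1lo at -0.185, 0.0609 and -0.524. Between groups of 2 arrays, replicates 1 and 2 gave the same correlation by construction, as at 0.219 for Id2KO with Id2KOBimKO. Such values are not separate checks of pairing. With a replicate block the counts were 42 (25 higher, 17 lower) between the WT populations and 5 for Id2KO against WT. They were 8 for the mean Id2 effect and 0 for Id2KOBimKO against WT. Some replicate numbers occur only in WT KLRG1lo, so those arrays have no partner in another group. The counts with a block therefore cannot show whether the samples are paired.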

Other observations

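The mean Bim effect and the look-up of genes that differ between KLRG1hi and KLRG1lo cells were chosen only after the results were seen, while the tests of fixed lists were planned. Genes lower in WT KLRG1hi than in KLRG1lo cells tended to be higher on the arrays labelled BimKO than in WT KLRG1lo: 37 of 38 were positive, with a median of 0.38 (adjusted p = 2.32e-17, and adjusted p = 0.106 with an estimated correlation). Of the 98 genes higher in KLRG1hi, 51 were positive and 47 negative, with a median of 0.03 (adjusted p = 0.658). Among memory precursor genes, Slamf6, a self-binding receptor of the SLAM family, was at 0.73, Myb at 0.63 and Bcl2 at 0.59, and none passed. The comparison shares the WT KLRG1lo arrays with the one that chose the genes. Shared noise in those arrays pulls the 38 genes to a negative sign and the 98 to a positive sign. The median of the 98 near 0 therefore cannot tell whether they moved. In the interaction the memory precursor list had a median of -0.42 with 0 of 20 positive (adjusted p = 0.000116, and adjusted p = 0.549 with an estimated correlation). It was 1 of 7 lists called for the interaction, 2 higher and 5 lower, and none held with an estimated correlation.

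Between arrays labelled Id2KOBimKO and Id2KO no gene outside the sex-linked ones passed in limma, and 116 of all genes tested had an unadjusted p under 0.05. The cytotoxic list had 0 of 18 values positive and a median of -0.30 (adjusted p = 0.000278), and the medians were 0.29 for B cell markers and 0.37 for red cell precursor markers. These calls were lost at adjusted p = 0.65 with an estimated correlation. The lists called between these groups numbered 10, of which 4 were higher and 6 lower, and none held with an estimated correlation. Ttbk2 was 6.05 ± 0.12 (SD, n = 5) in WT KLRG1lo, 6.25 in Id2KO, 7.15 ± 0.23 (SD, n = 2) on arrays labelled BimKO and 7.27 ± 0.04 (SD, n = 2) on arrays labelled Id2KOBimKO. It was the single gene outside the sex-linked ones to pass for the mean Bim effect (1.06, adjusted p = 0.00531), and it lies 76 tested genes from Bcl2l11 on the same chromosome.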
